A study of Homo sapiens with 6 samples.

How the data were processed

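Gene expression was measured by RNA-seq in BHT101, an established human cell line derived from an anaplastic thyroid carcinoma. Per the labels' protocols, the cells were transfected with plasmid using a lipid reagent and harvested after 48 h. Polyadenylated RNA was captured with beads, the libraries kept the strand by dUTP marking, and 150 nt paired-end reads were sequenced on an Illumina instrument. There were 6 libraries, 3 from cells given a control plasmid and 3 from cells given an SK4 plasmid. Samples were placed in groups by their titles. The treatment label of control replicate 3 writes BHT102 where its cell line label and source name write BHT101, so it was kept as a control. The labels do not say whether the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

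Per the submitters' processing notes, HISAT2 and the genome build GRCh38 were used. Their versions, the counting tool and the annotation release were not given in the sources used here. The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled to the mapped fragments of the library), rounded to 2 decimals, with 1 column per library and 32896 genes. No gene was at 0 in every library. FPKM removes differences in total depth and gene length, but not differences between libraries in how GC-rich or long transcripts are recovered. Gene-level values also hold no junction reads, so alternative splicing events were not analysed here. Reads from the plasmid and from the chromosomal copy of KCNN4 are added together in such a value.

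The depth was estimated from the deposited FPKM values. For 560 genes with a single exon shorter than 160 nt, the lowest values in a library are multiples of what 1 fragment is worth. Of the values worth up to 5 fragments, 100% were whole multiples within 0.1 in each library. The estimates were 35900000, 38600000 and 29800000 fragments for control replicates 1 to 3, and 36400000, 36800000 and 38300000 fragments for SK4 replicates 1 to 3. For a gene of 1 kb at 1 FPKM, counting error alone then gives a coefficient of variation of 16.1% to 18.3%. This covers counting error only, since the reads carry no molecular identifiers. The FPKM totals lay between 307702 and 309788. A count model was not used because the deposited unit is FPKM.

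Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, which left 11139. Values were taken as log2(FPKM + 0.5), and fold changes are on that scale, which understates the change of low genes. The groups were compared with limma 3.58.1 in R 4.3.3, with a trended and robust prior variance and group as the only term. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all tested genes. For KCNN4 an exact two-sided permutation test was added. The 36 gene lists, the tests, the rule for named genes and most of the alternative settings were fixed before the data were examined. Of the list members, 1067 of 1079 were in the table. Lists with at least 5 tested members (31 lists) were compared with all other tested genes by camera with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation, and fry, were run beside it. Calls within a list were also counted adjusted over the list alone, which leaves the number of lists uncorrected. Splicing factor genes of 4 lists were set against all other tested genes by Fisher's exact test, two-sided. That test was planned for called genes, and the same test at an unadjusted p below 0.05 was added to it.

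The rule for named genes took KCNN4, up to 8 called genes in each direction and, where a direction had none, the 5 genes with the smallest unadjusted p, leaving out clone names, pseudogenes and genes whose groups overlapped. Members of lists without called genes were allowed as values. The 5 genes with the smallest unadjusted p among the higher genes that were not called, the choice of 4 members with the smallest p from each list that camera called, and the members named in other groups were chosen after their values were seen. The values of some genes these choices took are not reported here. Genes of families with near-identical copies (GAGE2A, histone and MHC class I genes) and small RNAs inside other genes are uncertain, since the authors' handling of shared reads was not given in the sources used here.

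Coordinates, GC content and the length of the longest transcript came from GENCODE release 29 on GRCh38. The authors' annotation release may differ. Without the version suffix, 31726 of the 32896 identifiers matched, and 99.3% of the tested genes had a GC value. The alternatives covered the pseudocount, the filter on low values, the scaling, library weights, the prior variance, the replicate number as a term, a stricter threshold and leaving out each library. Added after seeing the data were a fit with the first within-group component as covariate, a fit without the 2 libraries that stood apart, a correction that removed each library's smooth trend along GC content, and camera with an estimated correlation in each of the other fits. The limma and camera steps were tested on simulated data with the means and spreads of the 11139 tested genes, 200 of them changed. Over 20 simulated datasets 89.8% of 2-fold and 67.1% of 1.5-fold changes were called. There were 5.9 false calls per dataset. Depth, ranges and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.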

Results

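The series asked which genes lie downstream of SK4, the calcium-activated potassium channel also called KCa3.1 and encoded by KCNN4, and it names differential expression and alternative splicing as its readouts. RNA-seq libraries were made from BHT101 thyroid carcinoma cells 48 h after transfection with a control plasmid (n = 3) or an SK4 plasmid (n = 3). The libraries held an estimated 29800000 to 38600000 fragments. Control replicate 3 was the shallowest, and 10735 genes reached 1 FPKM in it, against 10855 to 11147 in the other libraries.

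KCNN4 rose in the SK4 libraries. Its level was 8.36 ± 0.138 FPKM in the control libraries and 167 ± 18.3 FPKM in the SK4 libraries (SD, n = 3 each). Single control libraries held 8.31, 8.26 and 8.52 FPKM, and single SK4 libraries held 184.1, 147.7 and 169.2 FPKM. The fitted fold was 18.8 (95% confidence interval 16.6 to 21.3; log2 fold change 4.23; limma, adjusted p = 8.83e-07). With 3 against 3 libraries the exact two-sided permutation test gave p = 0.1, the smallest it allows. KCNN4 (ENSG00000104783) lies on the minus strand of chromosome 19 at 43766533 to 43781261 in GRCh38. The values do not separate plasmid transcripts from those of the chromosomal gene. The nearest protein-coding gene that was tested, SMG9, a component of nonsense-mediated decay, lies 11543 bp away and held 4.46 ± 0.0231 FPKM in the control and 4.67 ± 0.291 FPKM in the SK4 libraries. PLAUR, the urokinase receptor gene 95986 bp away, held 23.7 ± 0.821 and 24.5 ± 1.66 FPKM. Neither neighbour was called (adjusted p = 0.99997 for both, limma).

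**Figure D1:**
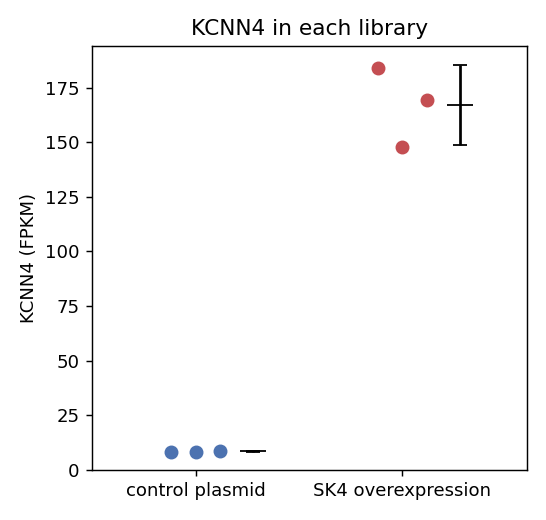
KCNN4 level in FPKM (vertical axis, from 0) in each of the 3 control plasmid and 3 SK4 overexpression libraries (points), with the group mean and SD beside them. The control libraries sit between 8.26 and 8.52 FPKM and the SK4 libraries between 147.7 and 184.1 FPKM.

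Beyond KCNN4 itself, no gene was called higher or lower among the 11139 tested. The calmodulin genes CALM2 and CALM3, whose product is the calcium sensor of the channel, had nearly equal levels in both groups. CALM2 was at 57.03 ± 6.78 FPKM in the control and 55.97 ± 4.92 FPKM in the SK4 libraries, and CALM3 at 57.8 ± 0.315 and 58.7 ± 1.27 FPKM. After KCNN4 the smallest adjusted p was 0.99997 (limma). At an unadjusted p below 0.05 there were 184 genes, 118 higher and 66 lower, where 557 would be reached by chance. The 3 SK4 values lay entirely above or below the 3 control values for 5.34% of the genes, against 10% by chance. A count below chance is not evidence that nothing changed. With the first within-group component as covariate, 811 genes had an unadjusted p below 0.05 (limma). That component was fitted to the same residuals, so the 811 cannot be set against chance either. The confidence interval of the fold change lay inside 2-fold in either direction for 99.6% of the tested genes, and inside 1.5-fold for 96.8%. Without control replicate 3 and SK4 replicate 2, which stand apart from the other libraries, 3 genes were called higher and 1 lower. KCNN4 and the small RNA genes SNORD99 and 7SK were higher, and SNORD4A was lower. SNORD4A is a short gene whose values rest on few fragments, and this fit had fewer libraries per group.

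**Figure D2:**
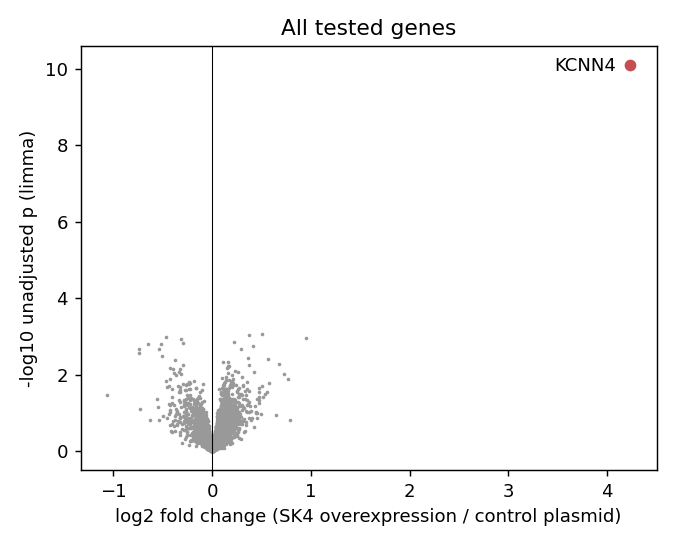
The log2 fold change between SK4 and control libraries (horizontal axis) against minus log10 of the unadjusted limma p (vertical axis) for the 11139 tested genes, 1 point per gene. KCNN4, at a log2 fold change of 4.23, is the single called gene, and 1 other gene lies beyond a log2 fold change of 1 in size.

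Among the genes that did not pass, the 5 lower ones with the smallest unadjusted p included GAGE2A, a cancer-testis antigen gene, and NMB, which encodes neuromedin B. GAGE2A was at 9.07 ± 0.579 FPKM in the control and 7.19 ± 0.235 FPKM in the SK4 libraries, and NMB at 8.55 ± 0.845 and 6.86 ± 0.19 FPKM. The others were the small nucleolar RNA genes SNORD4A (5.44 ± 0.316 and 3.11 ± 0.900 FPKM) and SNORD12C (6.57 ± 1.15 and 4.42 ± 0.226 FPKM), and C1orf53 (3.98 ± 0.408 and 3.07 ± 0.219 FPKM). Of the higher genes with the smallest unadjusted p, the metallothionein gene MT1M was at 0.763 ± 0.0896 FPKM in the control and 1.29 ± 0.0777 FPKM in the SK4 libraries. The stress-induced gene GADD45B was at 18.1 ± 0.502 and 21.2 ± 0.746 FPKM, the histone gene H2BC4 at 1.46 ± 0.0451 and 2.11 ± 0.211 FPKM, and the chemokine gene CCL3 at 5.33 ± 0.372 and 6.65 ± 0.117 FPKM. MIR3193, a microRNA gene, was at 0.697 ± 0.28 and 1.80 ± 0.326 FPKM. Small RNA genes are short, so such values rest on far fewer fragments than the same FPKM in a gene of 1 kb. The gene with the largest fold change in size that was not called was NDUFA4L2, which is induced in hypoxia. It ranged from 1.89 to 6.42 FPKM within the control libraries and from 1.01 to 2.58 FPKM within the SK4 libraries (log2 fold change -1.07, limma adjusted p = 0.99997).

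Gene groups differed little between the plasmids, and the highest ranked was the type I interferon response. Of its 42 tested members, 41 had a positive fold change, and the median member was 9.32% higher in the SK4 libraries (median log2 fold change 0.13). None of the 42 was called over all genes, or adjusted over the list alone. ISG15, an ubiquitin-like modifier induced by interferon, was at 816.6 ± 7.76 FPKM in the control and 880.1 ± 17.8 FPKM in the SK4 libraries. OASL, IRF7 and OAS1, an antiviral effector, an interferon regulator and an RNA sensor, had log2 fold changes of 0.16, 0.14 and 0.14. Each had all SK4 values above all control values, but these members were named for their small p. In the list 8 of 42 members were apart in this way, against 3.53% of all tested genes, the members not being independent. Camera ranked the list above the other genes (adjusted p = 1.72e-16), but not with an estimated correlation between its members (adjusted p = 0.315 with an estimated correlation). That estimate was 0.314, above the preset 0.01. The mean log2 level of the list was 4.37, 4.37 and 4.14 in control replicates 1 to 3 and 4.51, 4.32 and 4.46 in SK4 replicates 1 to 3, so the groups overlapped (exact two-sided permutation p = 0.3). Without control replicate 3 the median was 0.053, and without both control replicate 3 and SK4 replicate 2 it was 0.10.

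**Figure D3:**
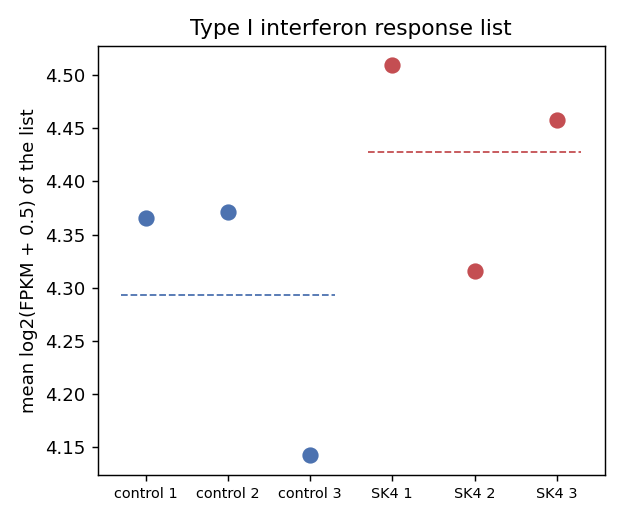
Mean log2(FPKM + 0.5) over the 42 tested members of the type I interferon response list (vertical axis, not starting at 0) in each library (points), with dashed lines at the group means. Control replicate 3 (4.14) and SK4 replicate 2 (4.32) are the lowest library of their groups, and the groups overlap.

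Inflammatory, immediate early, antigen presentation and histone genes also ranked higher by camera, with the median member 6.20%, 6.27%, 4.11% and 8.54% higher. In the NF-kB and inflammatory cytokine list 28 of 32 members had a positive fold change, with a median of 0.087 on the log2 scale (adjusted p = 5.39e-07; adjusted p = 0.350 with an estimated correlation). Its chemokine genes CXCL1 and CCL5 had log2 fold changes of 0.36 and 0.14, and NFKBIA, the feedback inhibitor of NF-kB, 0.12. In the immediate early list 19 of 22 members were positive, with a median of 0.088 (adjusted p = 1.60e-06; adjusted p = 0.402 with an estimated correlation). Among them were the phosphatase gene DUSP1 (28.1 to 28.9 FPKM in the control and 31.1 to 33.6 FPKM in the SK4 libraries) and the transcription factor genes KLF2 and JUNB, with log2 fold changes of 0.26 and 0.077. MHC class I and antigen presentation genes had a median of 0.058, with 13 of 15 positive (adjusted p = 1.40e-05; adjusted p = 0.315 with an estimated correlation). HLA-E was at 78.8 to 81.1 FPKM in the control and 85.3 to 85.5 FPKM in the SK4 libraries, and the peptide transporter gene TAP1 had a log2 fold change of 0.089. Histone genes had a median of 0.12, with 10 of 12 positive (adjusted p = 6.92e-05; adjusted p = 0.358 with an estimated correlation). No member of these 4 lists was called over all genes. Adjusted over the list alone, 2 histone genes were called, H2BC4 and H2BC12 (68.5 ± 1.91 FPKM in the control and 76.7 ± 2.93 FPKM in the SK4 libraries). For the library means, the exact two-sided permutation p was 0.2 for the NF-kB, 0.2 for the immediate early and 0.3 for the histone list. For MHC class I it was 0.1, the smallest the test allows. The mean level of each of these 4 lists was lowest in control replicate 3. That library was also lower over all tested genes, with a median log2 difference of -0.097 from the mean of the other controls. Without that library the medians were 0.044 for the NF-kB, 0.051 for the immediate early and 0.047 for the histone list, and 0.065 for MHC class I. The NF-kB median was 0.14 without control replicate 2, and the immediate early median 0.053 without SK4 replicate 1.

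The lists that ranked lower shifted by still less. Cytosolic ribosomal protein genes had a median log2 fold change of -0.021, with 10 of 77 positive (adjusted p = 2.38e-06; adjusted p = 0.315 with an estimated correlation). RPL3 was at 337.4 to 344.9 FPKM in the control and 329.4 to 336 FPKM in the SK4 libraries. S phase and DNA replication genes had a median of -0.030, with 11 of 40 positive (adjusted p = 0.000771; adjusted p = 0.816 with an estimated correlation), among them the thymidine kinase gene TK1 at -0.069. Hypoxia response and glycolysis genes had a median of -0.022, with 9 of 33 positive (adjusted p = 0.00519; adjusted p = 0.315 with an estimated correlation). In that list CA9, a carbonic anhydrase induced by hypoxia, held 2.32, 1.16 and 3.58 FPKM in the control and 0.85, 1.89 and 0.81 FPKM in the SK4 libraries, so the groups overlapped. Nuclear-encoded respiratory chain genes had a median of -0.013, with 21 of 54 positive (adjusted p = 0.0147; adjusted p = 0.315 with an estimated correlation). The estimate for the respiratory chain was 0.00821, below the preset 0.01, so a larger correlation is not why its call was lost. Estimates were also low for the ribosomal (0.0431) and MHC class I (0.0304) lists. A call lost with an estimated correlation is therefore not in itself evidence of correlated members. No member of these 4 lists was called over all genes or adjusted over the list alone. For the library means, the exact two-sided permutation p was 0.1 for the ribosomal list, the smallest the test allows. It was 0.6 for S phase, 0.2 for hypoxia and 0.2 for the respiratory chain. Without control replicate 3, or without SK4 replicate 1, the ribosomal (medians -0.0046 and -0.014), hypoxia (-0.018 and -0.0092) and respiratory chain (-0.010 and -0.012) lists were no longer called. Without control replicate 2 the S phase list was not called (median 0.0054), and its median was -0.073 without control replicate 3, -0.018 without control replicate 1 and -0.010 without SK4 replicate 2. Without control replicate 2 and without SK4 replicate 2, the hypoxia medians were -0.040 and -0.044 and the respiratory chain medians -0.0068 and 0.00061. The directional fry test called 0 of the 31 lists (lowest adjusted p = 0.646), and its test for change in either direction called 0 (lowest adjusted p = 0.188).

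**Figure D4:**
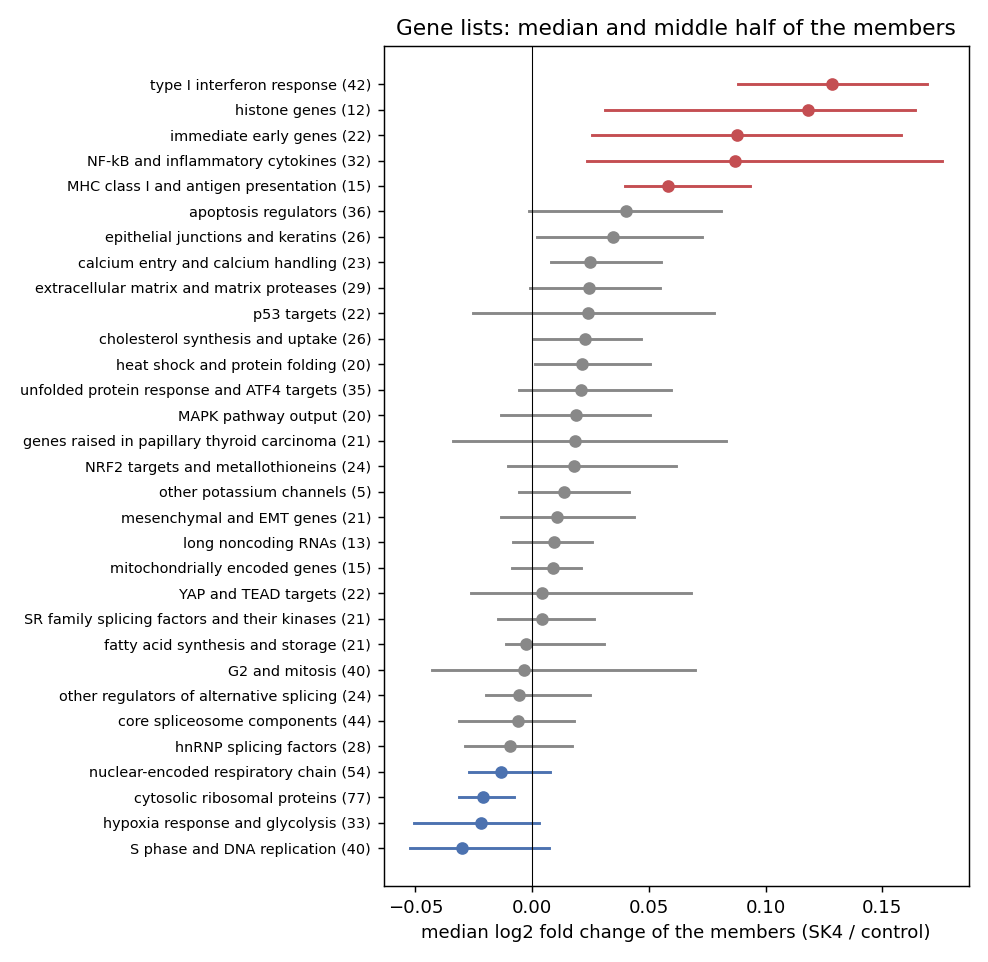
Median log2 fold change (points, horizontal axis) and middle 50% of the members (lines) of the 31 tested gene lists, with the number of tested members in parentheses. Red marks the 5 lists that ranked higher and blue the 4 that ranked lower by camera with the preset correlation, and grey the 22 not called; with an estimated correlation 0 were called.

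Genes that control splicing kept nearly equal levels between the groups, within narrow intervals. Tested were 117 genes for SR proteins and their kinases, hnRNPs, other splicing regulators and core spliceosome components. Of these, 0 were called and 0 had an unadjusted p below 0.05 (limma). Among the 11022 other genes, 1 was called and 184 had such a p. The planned Fisher's exact test compared called genes, and with 1 called gene in all it could not decide. An added test at the unadjusted level gave p = 0.269 (Fisher's exact test, two-sided). With 0 of the 117 at that level, this is the smallest p a shortfall could give. The median log2 fold change of the 117 genes was -0.0044. For all 117 the confidence interval of the fold change lay inside 1.5-fold in either direction. The smallest unadjusted p was that of SF3B5, a subunit of the SF3b complex, at 194.1 ± 7.42 FPKM in the control and 186.6 ± 1.14 FPKM in the SK4 libraries (limma, adjusted p = 0.99997). The kinase gene CLK1, which phosphorylates SR proteins, had the largest fold change in size of the group, a log2 fold change of 0.18 (2.16 to 3.41 FPKM in the control and 2.84 to 3.66 FPKM in the SK4 libraries). Camera called none of the 4 splicing lists on the FPKM values as deposited, with all 6 libraries weighted equally (adjusted p from 0.160 to 0.852). Some were called lower in other fits, and none of those calls held with an estimated correlation (adjusted p from 0.418 to 0.923 with an estimated correlation). None of the 4 was called higher. Without control replicate 2 the SR family, other regulator and hnRNP lists ranked higher without passing (medians 0.053, 0.045 and 0.031). The core spliceosome list ranked lower there. All 4 were called lower without control replicate 3 (hnRNP median -0.090 against -0.0096 with all libraries, adjusted p = 0.657 with an estimated correlation). The core spliceosome list was called lower without SK4 replicate 3 (median -0.013). Without control replicate 3 and SK4 replicate 2, the hnRNP and core spliceosome lists were called lower (medians -0.050 and -0.035). With all 6 libraries, the hnRNP and core spliceosome lists were called lower after the GC correction (medians -0.023 and -0.025). With library weights, the hnRNP list and the other splicing regulators were called lower (-0.052 and -0.045). Splicing events themselves were not analysed here.

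Calcium handling genes, which set the signal that opens the channel, were not called as a list (median log2 fold change 0.025, camera adjusted p = 0.538). The store-operated channel gene ORAI1 was at 22.9 ± 0.771 FPKM in the control and 24.0 ± 0.489 FPKM in the SK4 libraries, and its activator STIM1 at 4.85 ± 0.129 and 4.69 ± 0.219 FPKM. The 5 testable genes of the list of other potassium channels were not called either (median 0.014, adjusted p = 0.753). Genes raised in papillary thyroid carcinoma had a median of 0.018 over 21 members (adjusted p = 0.538), with KRT19 at 232 ± 13.6 and 240.4 ± 16.3 FPKM and TIMP1 at 614 ± 31.0 and 621.4 ± 14.1 FPKM. MAPK pathway output (median 0.019), mesenchymal and EMT genes (0.011), extracellular matrix and matrix proteases (0.025), epithelial junctions and keratins (0.034), apoptosis regulators (0.040), p53 targets (0.024), and G2 and mitosis genes (-0.0033) were not called, with adjusted p from 0.0782 to 0.973. The remaining lists, also not called, covered the unfolded protein response, heat shock, NRF2 targets, YAP targets, cholesterol and fatty acid synthesis, long noncoding RNAs and mitochondrially encoded genes (adjusted p from 0.178 to 0.886). The median, the mean and the camera rank differed in sign for 5 lists, none of them called: G2 and mitosis, long noncoding RNAs, SR family factors, fatty acid synthesis, and mesenchymal and EMT genes. Camera ranks a list against the other tested genes, and the median log2 fold change over all tested genes was 0.0108. Adjusted over the list alone, MT1M was called among the NRF2 targets and metallothioneins (0.763 and 1.29 FPKM), and GADD45B among the YAP and TEAD targets (18.1 and 21.2 FPKM). With the histone genes, 3 of the 31 lists had members called this way. That adjustment does not cover the number of lists, so a few such calls can arise by chance.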

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

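The fit with the within-group component, the fit without the 2 libraries that stood apart, the GC correction and the use of an estimated correlation in the other fits were chosen after seeing the data; the other alternatives were planned. KCNN4 was called higher in each of the 19 alternative fits, with a log2 fold change from 4.16 to 4.33 and an adjusted p of at most 0.000148, and was the single called gene in 18 of them. Without control replicate 3 and SK4 replicate 2, 3 genes were called higher and 1 lower, SNORD4A among them (log2 fold change -0.98). The values of this short gene rest on few fragments, and the cause of these calls was not tested. The number of genes at an unadjusted p below 0.05 was 184 of 11139 tested (1.65%). It was 905 of 11139 with library weights (8.12%) and 90 of the 5740 left by a filter at 5 FPKM (1.57%). The lowest share was 1.19%, with the replicate block. No splicing factor gene was called in any fit. The 5 lists that ranked higher were called in all 19, with medians for the interferon list from 0.053 (without control replicate 3) to 0.17 (without SK4 replicate 2) and adjusted p from 1.92e-24 to 5.33e-08. With an estimated correlation 0 lists were higher and 0 lower, and 0 were called in any of the 19 fits (lowest adjusted p 0.0635). The size of the correlation does not account for this in the respiratory chain list. Its estimate was 0.00821, below the preset 0.01, yet its unadjusted camera p rose from 0.00427 to 0.0419. For the other lists the cause was not tested. Without a filter on low values 2 lists were lower, and with a filter at 5 FPKM 8 were higher; the cause was not tested. The hnRNP and core spliceosome lists were called lower in 4 of the 19 fits each. The other splicing regulators were called lower in 2 and the SR family in 1. None was called higher, though all but the core spliceosome list ranked higher in some fits without passing. With an estimated correlation, 0 of the 11 lower calls held. The mitochondrially encoded, epithelial, G2 and mitosis, matrix, apoptosis, p53, YAP, NRF2 and unfolded protein response lists, not called with the settings of the report, passed in at least 1 of the other fits with the preset correlation, and 0 with an estimated one. Leaving out each library in turn gave 5 to 7 lists higher and 1 to 6 lower, with 1 lower without SK4 replicate 1, and 0 with an estimated correlation (lowest adjusted p from 0.371 to 0.648). Of the lower lists, with the preset correlation and in no fit with an estimated one, S phase kept its call in 18 of the 19 fits (adjusted p 1.46e-05 to 0.235), the ribosomal and hypoxia lists in 16 each (to 0.674 and 0.550) and the respiratory chain list in 13 (to 0.855). The respiratory chain list also turned in its rank to higher with library weights and without control replicate 3, without passing the threshold. Its medians there were -0.0104 and -0.0103. Camera ranks a list against the other genes, and the median over all tested genes was -0.0142 and -0.0211 in these fits. With the libraries left out in turn, the median of the list ran from -0.0184 to 0.000614. It was positive without SK4 replicate 2 with its rank still lower, where the median over all tested genes was 0.0240. With the replicate block, 1 gene was called higher and 0 lower and 5 lists were higher and 4 lower, so no call changed. The replicate numbers did not pair the samples, as deviations of same-numbered libraries correlated at 0.306, -0.410 and -0.154. The tests planned for raw counts were not run, as the unit is FPKM. Depth limits low genes most, with 16.1% to 18.3% counting error at 1 FPKM and 1 kb.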

Other observations

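In the patterns weighed here, the tests of exchanged labels and of a plasmid difference, the count of called lists over splits, the fits without the 2 libraries that stand apart, and the correction for GC content were chosen after the data were seen.

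BHT101 cells in both groups had little of the thyroid programme. Of 23 follicular differentiation genes in the table, 15 had a mean below 0.1 FPKM, among them thyroglobulin (TG), the TSH receptor gene (TSHR) and NKX2-1. PAX8 was at 0.333 ± 0.0833 FPKM in the control and 0.367 ± 0.0208 FPKM in the SK4 libraries. HHEX (7.68 ± 0.603 and 7.92 ± 0.541 FPKM), TFF3 (11.6 ± 0.863 and 11.4 ± 1.03 FPKM) and FHL1 (20.03 ± 1.80 and 19.98 ± 0.841 FPKM) were present. Of the neuroendocrine and C cell markers, DDC alone reached a mean of 1 FPKM (9.61 ± 0.561 and 9.24 ± 0.247 FPKM). Leukocyte markers were mostly near 0, with PTPRC at 0.00333 ± 0.00577 FPKM in each group, while LAPTM5 (14.8 ± 0.235 and 14.9 ± 0.372 FPKM), CD14 (3.98 ± 0.394 and 3.74 ± 0.441 FPKM) and CD3D (5.10 ± 0.481 and 3.87 ± 0.506 FPKM) were measured. Of the endothelial and fibroblast markers, LUM was at 25.04 ± 2.74 and 27.2 ± 4.22 FPKM, while COL1A1 and COL3A1 were below 0.1 FPKM. These marker lists had fewer than 5 tested members and were not tested as lists.

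The members of the interferon list differed widely in level in both groups. Of 46 members in the table, 42 had a mean of at least 1 FPKM. The interferon gene IFNB1 was at 0.243 ± 0.136 FPKM in the control and 0.31 ± 0.115 FPKM in the SK4 libraries, IRF9 at 0.317 ± 0.0751 and 0.383 ± 0.0777 FPKM, and MX2 at 3.72 ± 0.235 and 4.34 ± 0.11 FPKM. At the upper end, IFI6 lay between 1192 and 1285 FPKM, ISG15 between 811.5 and 900.1 FPKM, and CCL5, a chemokine gene of the NF-kB list, between 859.8 and 1011 FPKM. No untransfected library was among the samples, so whether transfection contributes to these levels was not tested.

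Control replicate 3 and SK4 replicate 2 stood apart from the other 4 libraries. The first component of the within-group deviations held 61.9% of their variance, with control replicate 3 at 0.69 and SK4 replicate 2 at 0.41 and the other libraries below 0. An exchange of the labels of these libraries is argued against by KCNN4, which was at 8.52 FPKM in control replicate 3, next to the other controls. Across genes, the loading on this component correlated with the GC content of the transcripts (Spearman rho 0.671, so that GC-rich transcripts were higher in these 2 libraries) and less with transcript length (rho -0.329, or -0.243 given GC content), genes not being independent replicates. A difference in the recovery of AT-rich transcripts between libraries is a candidate explanation, and no biological explanation was tested. CA9, NDUFA4L2 and NXPH4 went with the component within both groups: NXPH4 was at 2.93 FPKM in control replicate 3 against 2.21 and 1.34 FPKM in the other controls, and at 1.58 FPKM in SK4 replicate 2 against 1.08 and 1.14 FPKM.

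The small, broad shift of the interferon list may reflect SK4, the plasmids or the libraries. The 2 libraries that stand apart are argued against as the whole cause, since the median without them was 0.103 against 0.129 with all 6, although without control replicate 3 alone it was 0.0532. A general trend along GC content is also argued against: the median lay at percentile 100 of 10000 random lists matched on GC content, whose central 95% ran from -0.0080 to 0.033, and it was 0.105 after the GC correction. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. Of these, 4 splits, the real one included, gave a median as large in size (highest other 0.193). This median is not set against the other genes. Camera with the preset correlation gave the list an unadjusted p of 5.54e-18 in the real split. It gave 0.950, 3.14e-06 and 1.12e-05 in the others with a median as large. After the GC correction 1 of 10, the real split, gave a median as large (0.105, highest other 0.0973). A difference between the plasmids other than SK4 cannot be told apart from SK4, since plasmid and group are the same in these samples (0 libraries were without plasmid), and SK4 itself stays among the open explanations.

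The number of lists called with the preset correlation was 9 in the real split and up to 11 in the others, with 2 of the 10 splits, the real one included, giving as many. The 11 came from the split of control replicates 1 and 3 with SK4 replicate 2 from the rest. After the GC correction the real split gave 13 lists, and the others at most 9. In both cases the splits are too few for a share under 0.05.

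The simulation cannot settle whether a lack of power at 2-fold left KCNN4 alone among called genes. It changed 200 genes per dataset, which loosens the adjusted threshold, and drew the noise of each gene independently. Its share called may therefore overstate the power for a single changed gene. The confidence interval of the fold change did lie inside 2-fold for 99.6% of the tested genes. With 3 libraries per group and the spread of these libraries, 89.75% of simulated 2-fold changes were called, 67.1% of 1.5-fold and 1.38% of 1.1-fold changes, so shifts of the size seen in the interferon list would mostly be missed gene by gene. The splits are again too few for a share under 0.05: 1 of 10 gave as many called genes, the real one, and the highest of the others gave 0. After the GC correction the split of control replicates 1 and 3 with SK4 replicate 2 from the rest also called 1 gene. At an unadjusted p below 0.05 the real split gave 184 genes and another split 2642, the split of control replicates 1 and 2 with SK4 replicate 1 from the rest, which points to a structure among the libraries, since it sets the 3 libraries lowest on the within-group component against the other 3.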
